A study of Mus musculus with 32 samples.

How the data were processed

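RNA was measured in 32 libraries of Mus musculus, each made from an individual metaphase II egg or an individual 2-cell embryo. Per the labels' protocols, each egg or embryo was lysed in 5 uL of lysis buffer, cDNA was made with the SMART-seq v4 kit and 15 cycles of PCR, and the cDNA was fragmented and tagged with the Tn5 transposase. SMART-seq primes cDNA on poly(A) tails and amplifies it along the whole transcript, and it does not mark the strand. The libraries fall into 6 groups by their titles, with 3 WT eggs, 3 eggs labelled Trp53 KO, 8 WT early 2-cell embryos, 6 early 2-cell embryos labelled Trp53 MZ-KO, 6 WT late 2-cell embryos and 6 late 2-cell embryos labelled Trp53 MZ-KO. The design text states 6 replicates for the early 2-cell stage, where the WT group has 8 samples. MZ-KO stands here for embryos of knockout mothers and knockout fathers, per the labels' protocols. The targeted allele lacks exons 2 to 10 of Trp53, and the WT controls carried the floxed allele without the deletion. Early embryos were collected 28 to 32 hours and late embryos 48 hours after injection of the ovulation hormone hCG. The design text calls the samples biological replicates, but the labels do not say how many females gave the eggs and embryos of a group. The p-values therefore measure the spread between individual eggs or embryos, and siblings in a group would make them too small.

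The authors' deposited table holds 54532 genes with an FPKM value per library, that is, reads relative to gene length and to the depth of the library. Per the submitters' processing notes, the authors used TopHat2, DESeq, DESeq2 and the mouse genome build mm10, with no versions given in the sources used here. The authors' deposited table also gives their own comparison as a log2 fold change with its standard error and an adjusted p-value. The columns do not name its groups, which were inferred from the values as WT over MZ-KO late embryos. The log2 fold change correlated at 0.984 with the FPKM log ratio of WT over MZ-KO late embryos. The correlation was 0.176 for the early groups and 0.021 for the egg groups. The authors' mean FPKM columns were used to identify a column header with transposed letters, whose 6 columns gave the authors' mean of the late MZ-KO group within 3.3e-06. The other 3 value columns of that comparison were not used here. The column names give the group of each library but no replicate number, so libraries were numbered within their group in the order of the columns, and the numbers pair nothing.

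Low FPKM values showed how the authors' values were made. In genes spanning at most 2000 bp, at least 99.4% of low values in each library were whole multiples of the value of 1 read, within 0.1 read, when gene length was taken as the genomic span. With the exon length the share was at most 84.7%. Introns therefore count in the length of a gene, and FPKM values of genes with long introns are small. From the step per read, 7210000 to 27600000 reads stood behind the scale of each library. Genes nested in an intron of another gene showed that reads were counted over the whole span and on both strands. The host had at least as many reads as the nested gene in all libraries in 153 of 156 pairs on the same strand and in 243 of 248 pairs on opposite strands, against 181 of 404 for hosts drawn from other pairs. Reads of overlapping and antisense genes cannot be told apart in these values, and 85 of the 195 named genes overlap another annotated gene. Members of multicopy families can also share reads, so the values of single Zscan4, Tdpoz, Usp17l, Obox and Trav genes are uncertain. This also holds for Duxf3 and for the similar genes Hba-a1 and Hba-a2. Of the gene identifiers, 54495 were found in the reference annotation, GENCODE release M 21 for build mm 10, and 27 symbols that had been turned into dates were restored from it. The highest correlation between libraries of a group was 0.975, so no library was treated as a duplicate.

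Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes moderation (statmod 1.5.0). The pseudocount of 1 understates the change of low genes. Because the table holds FPKM and no counts, limma took the place of the count test that had been written down for a count table. Each genotype comparison used only the groups of that stage and the genes at FPKM 1 or more in at least as many libraries as the smaller group, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The WT stages were compared in the same way, and the difference between genotype effects of neighbouring stages was tested as a contrast of 4 groups. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

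The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. There were 16 lists with 419 members in all, taken from general knowledge and not from these samples: p53 targets, Dux-induced 2-cell genes, Dux and its reported regulators, early embryonic transcription factors, maternal oocyte genes, DNA damage response, apoptosis core, cell cycle, nucleolus and ribosome biogenesis, heat shock and stress, chr 11 neighbours of Trp53, histone genes, Y-linked genes, and markers of cumulus and granulosa cells, sperm, and blood and immune cells. Lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The fry test asked whether the members moved, on balance, in the same direction. For the p53 targets and the Dux-induced genes, the mean log2(FPKM + 1) of the members at FPKM 1 or more in at least 3 libraries was compared between genotypes by an exact two-sided permutation test. The text names Trp53, the 10 called genes with the largest rise and the 10 with the largest fall per genotype comparison, the 6 and 6 per stage comparison and per test of genotype by stage, and up to 4 members of each list with the smallest p. By this rule, clone-based symbols were counted and not named unless they belong to a list. Duxf3, and Zscan4d and Tcstv1 in late embryos, are list members named outside it. Examples from the gene groups chosen after the late calls were seen are outside it too. Gm47179 and Gm33962 are also named outside it and were chosen after their values were seen.

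The limma test was tested on simulated data for the real genes with 200 changed genes per comparison. Of the changes of 1 and of 2 on the log2 scale, it recovered 35.6% and 80% in eggs (6607 genes), 80.8% and 95% in early embryos (7675 genes), 60.6% and 93.4% in late embryos (8772 genes), 50.5% and 89.2% between WT eggs and early embryos (8619 genes), and 55.4% and 89.9% between WT early and late embryos (9319 genes). Between 3.11% and 7.43% of the simulated calls were wrong. A simulated list of 20 genes moved by 1 was found by camera in 100 of 100 simulations at each stage, and an unmoved list in 5, 4 and 2 of 100 in eggs, early and late embryos. Changed genes, single or in lists, were drawn only from the more highly expressed genes, so these shares do not hold for low genes. Each gene was simulated independently of the others. The simulations therefore do not show how often camera with the preset correlation calls an unmoved list of correlated genes.

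The alternatives were a pseudocount of 0.1, no filter on low values, a filter of FPKM 5, median-ratio scaling of the libraries, leaving out each library in turn, a fit over all 32 libraries, an added threshold of 1 on the log2 difference, moderation with neither trend nor robust estimation, and leaving out libraries whose number of detected genes lay over 3 median absolute deviations below their group. For the list means they were the pseudocount, the scaling, the median over members, leaving out each library and leaving out the Zscan4, Tdpoz and Usp17l families. Scaling factors for the list means came from all 32 libraries, and those for the gene comparisons from the libraries compared. After the data were seen, limma voom on the reads recovered from the steps, a filter of 20 such reads, removal of the trend with transcript length and thinning of the reads to a common depth were added. A blocked fit by replicate number was left out because the columns carry no numbers. The counts of called genes were also compared with those from at most 100 other groupings of the same libraries.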

Results

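Gene expression was measured in 32 single eggs and single 2-cell embryos of the mouse, as the authors' FPKM values, to compare WT with Trp53 knockout material across the egg, the early 2-cell and the late 2-cell stage. Trp53 encodes p53, a transcription factor that acts after DNA damage and other stress. Genes at FPKM 1 or more numbered 6088 to 6532 in the 3 WT eggs and 6308 to 6703 in the 3 eggs labelled Trp53 KO. The 8 WT early embryos had 6965 to 7990 such genes and the 6 early embryos labelled MZ-KO had 7325 to 7653. In the late stage, 7989 to 9417 genes reached this level in the 6 WT embryos and 9013 to 9745 in the 6 labelled MZ-KO. Between 7210000 and 27600000 reads stood behind the scale of a library (median 18300000). Of the variance over all libraries, 69.4% lay on the first principal component, on which late embryos lay between 103 and 138 and eggs and early embryos between -83.4 and -41.3. The library at -41.3 was WT early library 3, which also had the lowest median Spearman correlation with its group (0.808). All changes are differences of log2(FPKM + 1), which understate the change of low genes.

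Trp53 itself (ENSMUSG00000059552, build mm 10, chromosome 11, 69580359 to 69591873, plus strand) was lower in the early embryos labelled MZ-KO than in WT. Trp53 was not detectably lower in the eggs or the late embryos labelled knockout. Its FPKM was 6.05 ± 2.64 (SD, n = 8) in WT early embryos and 0.77 ± 0.326 (SD, n = 6) in those labelled MZ-KO, a log2 difference of -1.92 (SE 0.25, adjusted p = 0.00126), with all 6 MZ-KO libraries below the WT mean. In eggs it was 7.86 ± 2.13 (SD, n = 3) in WT and 8.19 ± 1.75 (SD, n = 3) in those labelled KO, a difference of 0.06 with a 95% interval of -0.52 to 0.64 (adjusted p = 0.956). In late embryos it was 3.24 ± 2.31 (SD, n = 6) in WT and 2.82 ± 1.38 (SD, n = 6) in those labelled MZ-KO, a difference of -0.03 with an interval of -0.80 to 0.74 (adjusted p = 0.955). In WT the difference from egg to early embryo was -0.40 (adjusted p = 0.33), and from early to late embryo Trp53 fell by 0.82 (SE 0.35, adjusted p = 0.0383). The genotype difference itself differed between late and early embryos by 1.88 (SE 0.44, adjusted p = 0.00348). Between early embryos and eggs it differed by -1.98 (SE 0.42, adjusted p = 0.044), a call that median-ratio scaling ended (-1.90, adjusted p = 0.0586). The principal transcript of 1771 nucleotides keeps 680 nucleotides, or 38.4%, outside the deleted exons 2 to 10, and the FPKM covers the whole gene span, so the value does not separate deleted from retained exons. Since the level of Trp53 goes against the labels of the eggs and of the late embryos, these groups are called by their labels throughout, and every direction drawn from them rests on those labels.

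**Figure D1:**
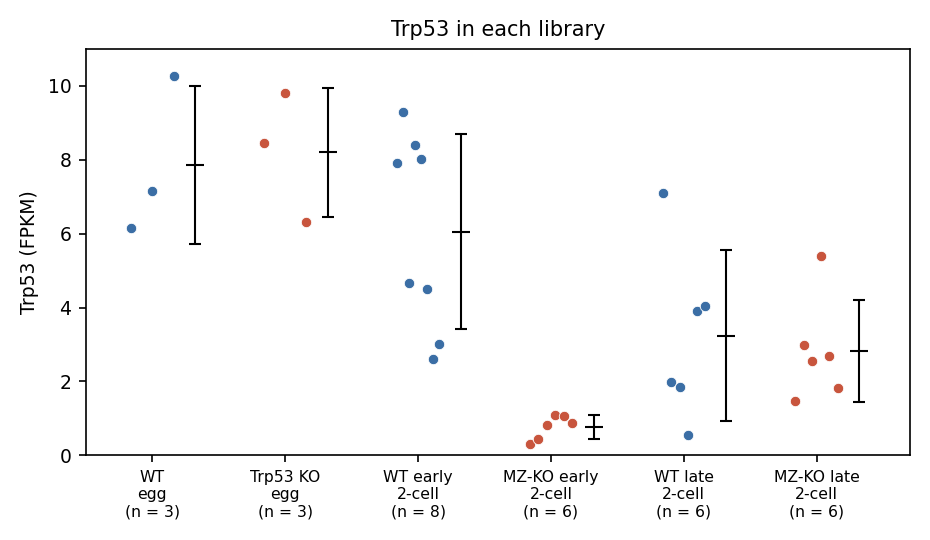
Trp53 expression (FPKM, vertical axis) in each of the 32 libraries by group, with the group mean and SD as bars; blue points are WT and red points are labelled knockout. The 6 early embryos labelled MZ-KO lie between 0.311 and 1.1 FPKM and the 8 WT early embryos between 2.6 and 9.29, while the groups overlap in eggs and in late embryos.

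The WT stages gave the normal course of the transition from maternal to embryonic RNA. From egg to early 2-cell embryo, the largest falls included transcripts stored in the oocyte and the largest rises included Dux-induced genes. The largest rises and falls given here and below leave out genes with clone-based symbols, unless these belong to a list. Mos, the kinase that holds the egg in meiotic arrest, fell from 391 ± 87.9 FPKM (SD, n = 3) to 8.96 ± 3.43 (SD, n = 8), a log2 difference of -5.37 (SE 0.34, adjusted p = 4.6e-07). The oocyte linker histone H1foo (-4.90), the oocyte factor Zar1 (-3.59), the spindle checkpoint gene Bub1b (-3.81) and the pseudogenes Smt3h2-ps4 (-4.90) and Mrps36-ps2 (-3.54) were the other large falls. The largest rises were in Gm2022, a Dux-induced gene at 37.1 ± 50.8 FPKM (SD, n = 8) in embryos and listed at 0 in all 3 eggs, in Derl3 (4.10), a component of protein degradation at the endoplasmic reticulum, in the carbonic anhydrase gene Car9 (3.99), in Usp17lb (3.90) and in the pseudogenes Obox4-ps28 (4.05) and Obox4-ps23 (3.91). In all 12 of these genes, each of the 8 embryos lay on the called side of the egg mean. These genes were picked as the largest called differences in the same libraries. Counts of libraries on the called side of such genes, here and below, are therefore no further evidence. Duxf3, the annotated Dux gene, rose from 0.035 ± 0.0606 (SD, n = 3) to 2.72 ± 1.6 FPKM (SD, n = 8).

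In all, 4423 of 8619 genes were called from egg to early embryo, with 2623 higher and 1800 lower. Of 33 tested Dux-induced genes 22 rose and 0 fell (26 rose when adjusted over the list alone; median 2.55; camera adjusted p = 1.2e-04, and adjusted p = 0.657 with an estimated correlation). Of 39 maternal oocyte genes 7 rose and 20 fell (8 and 20 adjusted over the list alone; median -0.62; adjusted p = 0.00232, and adjusted p = 0.657 with an estimated correlation). Of 16 DNA damage response genes 3 rose and 9 fell (3 and 10 adjusted over the list alone; adjusted p = 0.0325, and adjusted p = 0.657 with an estimated correlation). No other list was called by camera; of these, p53 targets had 5 rises and 3 falls among 16 and histone genes 4 and 1 among 11, the same numbers when adjusted over the list alone, and nucleolus and ribosome biogenesis 3 and 7 among 17 (3 and 8 adjusted over the list alone). Of the lists not called by camera, fry called apoptosis (adjusted p = 4.4e-04; 4 rises and 0 falls among 8), nucleolus and ribosome biogenesis (adjusted p = 0.00437), histone genes (adjusted p = 0.00508), heat shock and stress (adjusted p = 0.0105) and early embryonic transcription factors (adjusted p = 0.023). Median-ratio scaling moved the median difference of all tested genes from 0.15 to -0.00 and the split of calls to 2321 higher and 2394 lower. With a filter of FPKM 5 the count was 2011.

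From early to late 2-cell embryo, the change in WT covered most tested genes. Obox8, of the oocyte homeobox family, rose by 7.99 (SE 0.41, adjusted p = 6.3e-11) from 1.64 ± 2.78 FPKM (SD, n = 8) to 505 ± 96.2 (SD, n = 6), followed by the alkaline phosphatase gene Alppl2 (7.70), Impdh2-ps (7.49), Cd63-ps (7.44), the Dux-induced gene Gm4850 (7.30) and the metallothionein gene Mt1 (7.20). The largest falls were in the oocyte gene Rfpl4 (-6.83), in Bcl2l10 (-6.75), a member of the Bcl-2 family stored in oocytes, in the immunoglobulin lambda segments Iglj2 (-6.40) and Iglj3, the latter at 105 ± 44.3 FPKM (SD, n = 8) in early embryos and listed at 0 in all 6 late ones, in the G protein regulator Rgs2 (-6.43) and in AU022751 (-5.86). Iglj2 and Iglj3 each span 38 bp and overlap another annotated gene, so their values rest on reads of uncertain source. All 6 late embryos lay on the called side of the early mean in each of the 12 genes. Of 9319 genes 7923 were called, 4346 higher and 3577 lower. Of 38 maternal oocyte genes 34 fell and 1 rose, the same numbers when adjusted over the list alone (median -2.52; adjusted p = 2.5e-09, and adjusted p = 0.321 with an estimated correlation). Of 24 nucleolus and ribosome biogenesis genes 23 rose and 0 fell, also when adjusted over the list alone (median 1.88; adjusted p = 2.8e-05, and adjusted p = 0.148 with an estimated correlation). Duxf3 fell by 1.78 (SE 0.22, adjusted p = 1.8e-06), and of 35 Dux-induced genes 15 rose and 4 fell, also when adjusted over the list alone. Among 12 early embryonic transcription factors 7 rose and 4 fell, and among 12 histone genes 3 rose and 8 fell, again the same when adjusted over the list alone. Camera did not call these lists (adjusted p = 0.543 and 0.353) and fry did (adjusted p = 5.8e-09 and 1.8e-04), as it did all 12 lists tested (adjusted p at most 0.0218). The count was 3554 with a filter of FPKM 5, 15824 with no filter and 13778 with the filter of 20 recovered reads.

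In eggs, the comparison of those labelled Trp53 KO with WT asked whether loss of p53 in the mother alters the stored RNA. It called 22 genes, 14 higher and 8 lower. Most were not protein-coding genes: 6 of the rises and 2 of the falls were pseudogenes, and 7 rises and 4 falls were of other non-coding or gene segment classes. The 7 rises without a clone-based symbol were in the T cell receptor alpha segments Trav13-3, Trav9-2 (2.77), Trav13d-3, Trav7-6 (2.33) and Trav3-1 (1.44, the smallest of the 14 rises) on chromosome 14, in the ribonuclease gene Rnase6 on the same chromosome (2.31, SE 0.17, adjusted p = 0.00123) and in Mir7654. Trav13-3 was at 21.3 ± 11.7 FPKM (SD, n = 3), Trav13d-3 at 5.54 ± 2.86 (SD, n = 3) and Mir7654 at 2.22 ± 0.697 (SD, n = 3) in eggs labelled KO, and all 3 genes were listed at 0 in the 3 WT eggs. Mir7654 spans 70 bp and overlaps another annotated gene, so its value rests on few reads of uncertain source. Cnpy4 was the named gene that fell, from 27.8 ± 2.17 (SD, n = 3) to 6.31 ± 1.35 FPKM (SD, n = 3), a difference of -1.99 (SE 0.21, adjusted p = 0.00998). In all 8 of these genes the 3 eggs labelled KO lay on the called side of the WT mean.

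No list member was called in eggs over all genes. Adjusted over the list alone, Ccne1 of the cell cycle list (0.84, adjusted p = 0.161 over all genes) was higher, Cd68 of the chr 11 neighbours of Trp53 (-1.13, adjusted p = 0.32 over all genes) was lower and 0 members of the other lists were called. The smallest camera adjusted p over 11 lists was 0.283. Among 9 tested p53 targets, the differences of the cyclin-dependent kinase inhibitor Cdkn1a (0.10, adjusted p = 0.913), Btg2 (-0.15), Ddb2 (-0.18) and Gtse1 (0.20) were not called. The 4 tested Dux-induced genes and 39 maternal oocyte genes had medians of -0.14 and 0.04. Of the cumulus and granulosa cell markers 1 was tested (0.38), and of the sperm, blood and immune cell and Y-linked lists 0 were. The count of 22 is small against the 577 genes at an unadjusted p below 0.05, and it ran from 6 to 38 when any egg was left out. It fell to 6 with no filter, 8 with a pseudocount of 0.1, 14 with a filter of FPKM 5, 12 with the filter of 20 recovered reads and 12 without KO egg library 3, the library with the fewest detected genes for its group. Falls outnumbered rises with the filter of FPKM 5 (6 higher, 8 lower) and without KO egg library 1 (17 higher, 21 lower). Rises outnumbered falls under the other alternatives and left-out eggs.

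In early 2-cell embryos, those labelled MZ-KO had lower Trp53 and a modest set of other changes, most of them rises. The splicing factor gene Crnkl1 rose from 1.46 ± 0.9 FPKM (SD, n = 8) to 16 ± 2.12 (SD, n = 6), a difference of 2.84 (SE 0.19, adjusted p = 8.4e-07). The other large rises were in Erich5 (1.89), n-R5s185 (1.73), Dynlt1-ps1 (1.54), the Dux-induced gene Tcstv3 (1.54), the maternal factor Zar1 (1.52), Snora47 (1.45), the olfactory receptor gene Olfr877 (1.37), the potassium channel gene Kcnk18 (1.37) and the DNA damage histone H2afx (1.33). Besides Trp53, falls were found in Duoxa2 (-2.17), a maturation factor of a dual oxidase, in Mir8114 (-1.38), in the glutathione cycle enzyme gene Ggct (-1.34, SE 0.10, adjusted p = 5.4e-06), in the glutamine synthetase gene Glul (-1.18), in Peak1os (-1.16), Ralgds (-1.08), Ccdc186 (-0.94), Obox4-ps33 (-0.93) and the keratin gene Krt18 (-0.89). All 6 embryos labelled MZ-KO lay on the called side of the WT mean in each of these 20 genes. Mir8114 spans 111 bp and overlaps Glul on the same strand, so the falls of Mir8114 and Glul can rest on the same reads. With median-ratio scaling the call of Olfr877 ended (adjusted p = 0.0516).

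Of the p53 targets, 0 of 15 tested members were called at this stage, over all genes or adjusted over the list alone, although Trp53 RNA was lower. Plk2 differed by -0.66 (adjusted p = 0.107), Cdkn1a by -0.86 (adjusted p = 0.173), Ccng1 by -0.54 (adjusted p = 0.182) and Mdm2, which encodes the ligase that degrades p53, by 0.27 (adjusted p = 0.336). The Dux-induced genes had 26 of 31 tested members below WT with a median of -0.70, but the member that was called, Tcstv3, rose. Adjusted over the list alone, 2 rose and 0 fell, the second being Tcstv1 (2.72, SE 0.75, adjusted p = 0.0587 over all genes). Camera gave an adjusted p of 3.5e-04 downward for this list, and an adjusted p = 0.984 with an estimated correlation. Duxf3 itself was at 4.49 ± 3.36 FPKM (SD, n = 6) in embryos labelled MZ-KO and 2.72 ± 1.6 (SD, n = 8) in WT, a difference of 0.40 (SE 0.39, adjusted p = 0.605). None of the 16 tested members of the list of Dux and its regulators was called.

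Among the maternal oocyte genes 3 of 39 rose and 0 fell (5 rose adjusted over the list alone), namely Zar1, H1foo (1.04, adjusted p = 0.0215) and Tle6 (1.26, adjusted p = 0.0304), a member of the subcortical maternal complex. Cdt1 (0.83) and Aurkc (0.68), genes of replication licensing and of meiotic and early embryonic division, rose among 31 cell cycle genes (2 rose adjusted over the list alone). H2afx was the 1 of 13 DNA damage response genes that rose, Npm1 (0.48) the 1 of 14 nucleolus and ribosome biogenesis genes and Hspe1 (0.61) the 1 of 16 heat shock and stress genes; adjusted over the list alone the rises numbered 1, 1 and 2. Scaling by median ratios ended the call of Npm1 (adjusted p = 0.0662). The fry test gave an upward adjusted p of 0.0365 for heat shock and stress genes, while camera gave an adjusted p of 0.815. No member of the apoptosis, early embryonic transcription factor, chr 11 neighbour, histone or cumulus and granulosa cell lists was called over all genes; adjusted over the list alone, Tfap2c (0.51, adjusted p = 0.0587 over all genes) was higher among the transcription factors and Hist1h1a (-0.93, adjusted p = 0.0704 over all genes) lower among the histone genes. Of the sperm, blood and immune cell and Y-linked lists 0 members were tested.

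In all, 252 of 7675 genes were called in early embryos, 198 higher and 54 lower, and 58 of them differed by 1 or more on the log2 scale. The split was 141 higher and 90 lower with the trend on transcript length taken out and 146 and 61 with median-ratio scaling. The count was 56 with no filter and 430 in the fit over all libraries, and without MZ-KO library 2, 3, 5 or 6 it was 131, 136, 130 or 105. Some genes given in the last part had values that fell into sets of libraries within an early group, so these libraries may not be independent.

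In late 2-cell embryos, those labelled MZ-KO differed from WT in many genes, although no difference in Trp53 RNA was detected. Ier3, an immediate early gene, rose from 1.34 ± 2.98 FPKM (SD, n = 6) to 18.8 ± 5.15 (SD, n = 6), a difference of 3.64 (SE 0.47, adjusted p = 1.9e-04). The imprinted growth regulator Phlda2 (3.56), the nucleotidase gene Nt5c (3.36), the respiratory complex I genes Ndufb10 (3.14) and Dmac1 (3.11), the latter an assembly factor, Dnajb3 (2.99), Dnajc19-ps (2.99), the immunoproteasome subunit gene Psmb10 (2.98), Fkbp11 (2.92) and the germline gene Tex19.2 (2.90) were the other large rises. The largest fall was in Calhm3 (adjusted p = 2.2e-05), which was at 25.9 ± 15.6 FPKM (SD, n = 6) in WT and listed at 0 in all 6 embryos labelled MZ-KO. It was followed by the microRNA genes Mir293 (-3.39) and Mir294 (-2.88), by Rfpl4b (-2.96), Arl4d (-2.96), Defb25 (-2.76) and AA414992 (-2.67), and by the Dux-induced genes Gm2022 (-3.20), Gm2016 (-2.92) and Gm4027 (-2.84). Mir293 and Mir294 span 80 and 84 bp close together on chromosome 7, and each overlaps another annotated gene. Their reads are of uncertain source, and their falls need not be separate. In each of these 20 genes, picked by the size of their difference in these libraries, all 6 embryos labelled MZ-KO lay on the called side of the WT mean.

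Of 31 tested Dux-induced genes 20 fell and 1, Tcstv1 (adjusted p = 0.0133), rose in the late embryos labelled MZ-KO (22 fell and 2 rose adjusted over the list alone; median -1.44). Camera gave the list an adjusted p of 5.3e-07, and an adjusted p = 0.402 with an estimated correlation, fry gave an adjusted p of 0.0113, and the difference of the list mean did not hold after adjustment (exact permutation p = 0.0173, adjusted p = 0.104). Tdpoz3 fell from 7.15 ± 4.72 (SD, n = 6) to 0.287 ± 0.462 FPKM (SD, n = 6), a difference of -2.54 (SE 0.34, adjusted p = 2.2e-04), and the chromatin reader gene Sp110 (-1.09), Tmem92 (-1.67), Pramef6 (-1.91) and Zscan4d (-1.71) also fell. Of 17 members of the list of Dux and its reported regulators 1 rose and 4 fell, the same when adjusted over the list alone: Pcgf6, of a Polycomb complex, rose by 0.75, and Zfp217 (-1.20), Nelfa (-0.55) and Trim28 (-0.58), a corepressor, were among the falls.

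Of 18 tested p53 targets 4 rose and 5 fell in late embryos (5 and 5 adjusted over the list alone; median -0.41; camera adjusted p = 0.329). With median-ratio scaling of the late libraries 3 rose and 6 fell (median -0.53). With scaling factors taken from the libraries of all stages, the list mean differed by -0.34 (exact permutation p = 0.00433, not adjusted over the list means). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.16 (SE 0.38, adjusted p = 0.00115), from 5.84 ± 3.8 (SD, n = 6) to 26.6 ± 8.15 FPKM (SD, n = 6), and Mdm2 rose by 0.96 (SE 0.20, adjusted p = 0.00316). The glycolysis regulator gene Tigar (-1.14, adjusted p = 4.3e-04) and the stress gene Gadd45a (-1.33, adjusted p = 0.00302) fell. Among early embryonic transcription factors 4 of 12 fell and 1 rose (5 and 1 adjusted over the list alone): Nr5a2 (-0.79), Obox3 (-1.05) and Klf17 (-1.02) fell and Klf4 (0.94) rose, with a camera adjusted p of 0.116 and a fry adjusted p of 0.0113. Of 16 heat shock and stress genes 8 fell and 1 rose, also when adjusted over the list alone; the chaperone gene Hspa8 (-1.90), the stress transcription factor gene Ddit3 (-1.88) and the superoxide dismutase gene Sod2 (-0.74) fell, and the mitochondrial chaperone gene Hspd1 (1.08) rose, with adjusted p values of 0.0537 from camera and 0.0113 from fry. Of 28 nucleolus and ribosome biogenesis genes 7 fell and 1 rose, also when adjusted over the list alone; Rrp9 (-0.95), Fbl (-0.78) and Nop56 (-0.71) fell and Wdr12 (0.99) rose (camera adjusted p = 0.0537).

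Apoptosis genes gave 4 rises and 0 falls among 12, also when adjusted over the list alone. These were cytochrome c (Cycs, 1.42), the caspase gene Casp6 (adjusted p = 0.00435), Bad (0.94) and the caspase inhibitor gene Xiap (0.48), and camera gave an adjusted p of 0.182 and fry of 1.1e-04. The call of Xiap ended with median-ratio scaling (adjusted p = 0.0861). Of 32 cell cycle genes 3 rose and 6 fell, also when adjusted over the list alone, with Cdk4 higher (1.49) and the replication clamp gene Pcna (-1.02), Cdk1 (-1.01) and Cdc20 (-1.30) lower. In the DNA damage response list 2 of 15 rose and 3 fell (3 and 3 adjusted over the list alone), with Xrcc6 (0.67) higher and Brca2 (-0.70), Wee1 (-0.79) and Msh6 (-0.60) lower. Of 28 maternal oocyte genes 1 rose, Dazl (1.22), and 1 fell, Zar1l (-0.86), and 0 were called when adjusted over the list alone. The chr 11 neighbours of Trp53 gave 1 rise, Tnfsf13 (0.92), and 2 falls, Polr2a (adjusted p = 0.00421) and Eif5a (-0.55), among 18 (1 and 1 adjusted over the list alone). Of 10 histone genes 1, the histone mRNA binding gene Slbp (0.65), rose, also when adjusted over the list alone; this call ended with median-ratio scaling (adjusted p = 0.0781), under which 1 other member fell. Under that scaling the medians of the DNA damage response list (0.14 to -0.01), the cell cycle list (0.03 to -0.17), the chr 11 neighbours (0.06 to -0.10) and the histone genes (0.08 to -0.06) changed sign.

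Markers of other cell types moved in late embryos as well. The 4 tested blood and immune cell markers all rose, also when adjusted over the list alone: the hemoglobin genes Hba-a2 (2.08, adjusted p = 8.3e-04) and Hba-a1 (1.94), Coro1a (1.86) and Cd52 (0.62). Hba-a2 was at 46.1 ± 26.5 FPKM (SD, n = 6) in embryos labelled MZ-KO and 8.8 ± 2.07 (SD, n = 6) in WT, where it had risen by 2.41 from the early stage. Hba-a1 and Hba-a2 can share reads, so the 4 rises are not independent. The sperm marker Prm1 fell (-0.70, adjusted p = 0.0493), the cumulus and granulosa cell marker Amhr2 differed by -0.34 (adjusted p = 0.223) and was called lower with median-ratio scaling (-0.51), and of the Y-linked genes 0 were tested. Prm1 spans 9514 bp and overlaps 2 annotated genes, so its value need not reflect sperm RNA. The 1 member of the sperm list tested from WT early to late embryos rose by 3.78.

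**Figure D2:**
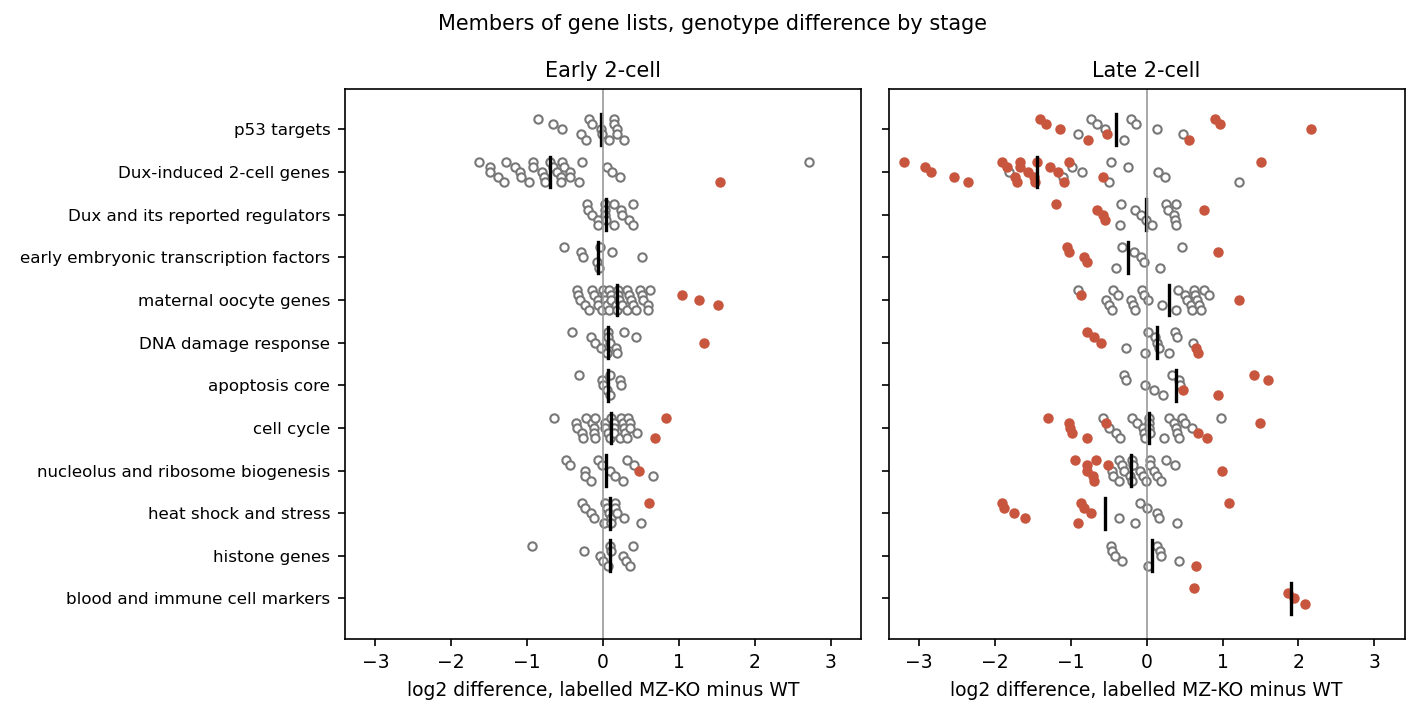
Log2 difference (labelled MZ-KO minus WT, horizontal axis) of each tested member of the gene lists in early and late 2-cell embryos; filled red points are called genes, open points are not, and black bars are list medians. In the late panel 20 of 31 Dux-induced genes are called below 0 around a median of -1.44, and p53 targets are called on both sides.

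In all, 2802 of 8772 genes were called in late embryos, 1624 higher and 1178 lower, and 1304 of them differed by 1 or more on the log2 scale. With median-ratio scaling, which moved the median difference of all tested genes from 0.07 to -0.07, the split turned to 1124 higher and 1630 lower, and the count was 1502 with a filter of FPKM 5. The authors' deposited table gives an adjusted p-value for 23684 genes in this comparison, of which 4881 lie below 0.05, 2506 higher in MZ-KO and 2375 higher in WT. Of the 2802 genes called here, 2225 are also below 0.05 in the authors' deposited table, all of them in the same direction. The direction of the authors' comparison was inferred from these same libraries, so the shared direction is no independent evidence. In the authors' deposited table the log2 fold change of WT over MZ-KO is -1.97 for Cdkn1a, 2.26 for Hspa8 and 0.34 for Trp53, whose adjusted p there is 0.694. Of the called genes named above for late embryos, Ier3 (-3.67, adjusted p = 0.104) and Mir294 (3.54, adjusted p = 0.0897) are not below 0.05 in the authors' deposited table. Tcstv1 and Zscan4d were not included in this comparison. In the authors' deposited table Amhr2 (0.59, adjusted p = 0.0233) and H2afz (0.57, adjusted p = 0.0118), not called here, are below 0.05.

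The genotype difference changed between the stages in 2363 of 11558 genes from early to late embryos, 1392 with a higher and 971 with a lower late difference. With median-ratio scaling, which moved the median of all tested genes from 0.05 to -0.10, the split was 859 and 1676, and the count was 1194 with a filter of FPKM 5. The largest positive changes were in Ier3 (4.06), Nt5c (3.33), Psmb10 (3.18), Ndufb10 (3.11), Phlda2 (3.11) and Rnf138rt1 (3.08). The largest negative changes were in Calhm3, which was listed at 0 in all late embryos labelled MZ-KO, Mir7036b (-3.42), Mir293 (-3.39), Mir294 (-3.19), Crnkl1 (-3.12, adjusted p = 8.0e-08) and Snora31 (-3.03). Mir7036b spans 63 bp and overlaps another annotated gene, so its reads are of uncertain source too. Crnkl1 was 2.84 higher in early embryos labelled MZ-KO and stood at 18.8 ± 3.09 (SD, n = 6) against 23.3 ± 5.99 FPKM (SD, n = 6) in WT late embryos. The change of Cdkn1a was 3.02 (adjusted p = 3.0e-04) and that of Mdm2 0.69 (adjusted p = 0.0475).

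From egg to early embryo the genotype difference changed in 34 of 9676 genes, 21 upward and 13 downward. The named genes were Cnpy4 (2.92), Crnkl1 (2.73), Gas5 (2.58), Rpe (2.02), Stk25 (1.71) and Dusp23 (1.71) upward and Alyref2 (-2.72), Trp53 (-1.98), Rbm44 (-1.44), Rap2b (-1.03), Ggct (-1.02) and Rttn (-0.81) downward. The calls of Ggct and Trp53 ended with median-ratio scaling (adjusted p = 0.0613 and 0.0586). The count rests on single eggs: without KO egg library 1, 2 or 3 it was 75, 9 or 13, and without WT egg library 1, 2 or 3 it was 13, 14 or 15. It was 11 with no filter, 21 with a filter of FPKM 5 and 55 with voom on the recovered reads.

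The mean over the 37 Dux-induced genes at FPKM 1 or more in at least 3 libraries was 3.46 ± 0.72 (SD, n = 6) in WT late embryos and 2.38 ± 0.29 (SD, n = 6) in those labelled MZ-KO. The difference of -1.08 had an exact permutation p of 0.0173, which is 0.104 after adjustment over the 6 list means, so it did not hold after that adjustment. In early embryos the list mean was 2.46 ± 0.84 (SD, n = 8) in WT and 1.93 ± 0.68 (SD, n = 6) in those labelled MZ-KO, a difference of -0.53 (exact permutation p = 0.23). This was -0.33 without WT early library 3 (exact permutation p = 0.39). It was -0.33 without the Zscan4, Tdpoz and Usp17l families (exact permutation p = 0.417) and -0.81 with a pseudocount of 0.1 (exact permutation p = 0.206). The early and late differences did not differ detectably from each other (-0.55, permutation p = 0.377 over 100000 resamples). In eggs the difference was 0.02 (exact permutation p = 0.4, where 3 against 3 eggs allow no p below 0.1). The mean of the 19 p53 targets differed by 0.05 in eggs (exact permutation p = 0.3), -0.11 in early embryos (exact permutation p = 0.214) and -0.11 in late embryos (exact permutation p = 0.394). The change of the p53 target difference from early to late was 0.00 (permutation p = 0.981).

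**Figure D3:**
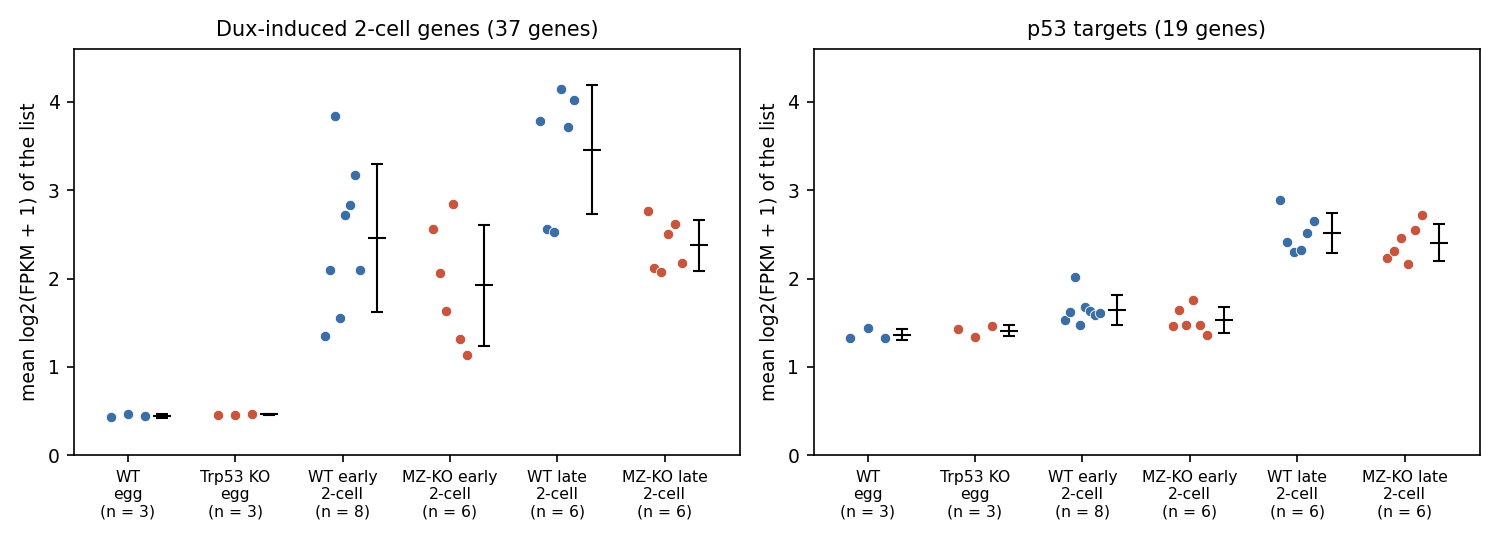
Mean log2(FPKM + 1) of the 37 Dux-induced genes (left) and the 19 p53 targets (right) in each library by group, with the group mean and SD as bars; blue points are WT and red points are labelled knockout. WT late embryos span 2.53 to 4.15 for the Dux-induced genes and those labelled MZ-KO 2.07 to 2.76.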

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

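The tests of swapped egg labels, of reads from outside the deletion, of neighbouring calls, of calls on a single chromosome, of like size in eggs and early embryos, and of progress measured within embryos labelled knockout were chosen after the results they bear on were seen. The test of like size replaced an earlier form after its result was known. That form counted egg calls also called in early embryos and gave 0 of 18 tested genes in the same direction and 1, Cnpy4, in the opposite direction, but a missed threshold excludes nothing.

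Other groupings of the same libraries were used to ask whether chance can be excluded for each count of called genes. For early embryos (252 genes, highest other grouping 6), late embryos (2802, highest other 6), WT egg to early embryo (4423, highest other 46) and WT early to late embryo (7923, highest other 6128), 1 of 100 groupings, the real one, gave as many genes. Chance can therefore be excluded for these counts, for libraries taken as independent. For the late against early genotype difference (2363, highest other 369) and the early against egg genotype difference (34, highest other 5), 1 of 100, the real one, also gave as many. There genotype was shuffled within each stage, which removes every genotype effect. Those groupings therefore cannot exclude chance where genotype effects are alike in both stages. The groupings exchange single libraries and do not exclude chance differences between mothers, which the labels do not give; Gm47179, picked after its values were seen, was at 103, 94.2, 96.2, 27.6, 26.8 and 25.1 FPKM in early MZ-KO libraries 1 to 6. The grouping with 6128 genes exchanged 1 library of each stage, and the next highest gave 1 gene. For eggs, the 10 possible groupings are too few for a share under 0.05; the real count was 22 and the highest other was 1.

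The genotype difference of Trp53 differed between stages by 1.88 for late against early embryos and by -1.98 for early embryos against eggs. A swap of WT and KO labels among the eggs would need higher Trp53 in the eggs labelled KO by about the size of the early difference, and the upper end of the 95% interval of the egg difference was 0.64, which argues against it. Reads from exons outside the deletion, at the same share in every stage, would give like differences in early and late embryos, and the 95% interval of 1.88 ran from 0.98 to 2.79. A share of such reads that differs by stage, a mix-up with samples outside these groups and eggs or embryos that kept the undeleted allele stay open, since FPKM over the whole gene does not separate the exons. No biological explanation was tested.

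Of the 22 genes called between eggs, 10 had another call 0.1 to 5 Mb away, against a median of 2 and a highest of 11 in 10000 random draws (permutation p = 9.0e-04), but without the Trav genes it was 4 of 17 (permutation p = 0.123), so linked segments of strain variants stay open. Reads shared within the Trav family, which can bear on its 5 called genes alone, also stay open for those. Of the 34 calls for early embryos against eggs, 15 lay on chromosome 1, which holds 6.36% of tested genes, where 10000 random draws reached at most 10 on any chromosome (permutation p = 1.0e-04, the smallest they can give), consistent with linked segments that differ between the mice used, which had a mixed background. The median early difference in the egg direction was 0.17 over the 18 egg calls tested in early embryos, against a median size of 2.25 in eggs. The SD between genes was 0.91 and the range -1.34 to 1.62, with 10 of 18 in the egg direction. Those genes were selected for large egg differences, which favours a smaller early value. Egg calls such as Trav13-3, Rnase6 and Gm47179, picked after their values were seen, also varied widely between early libraries of the same group. The early difference therefore depends in part on which embryos a group holds, and it cannot decide on a genotype effect of like size in both stages. Trav13-3 and Rnase6 were present in some WT early libraries and nearly absent in others, so differences of this kind occurred within WT. An effect of genotype in eggs alone stays open, as the design offers it and no test here separates it from the strain of the mothers.

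The 2802 calls in late embryos changed little in number with corrections for depth and length. With all libraries thinned to the same depth 2746 genes were called, and with the trend on transcript length taken out 2756, which argues against either as the whole cause. Slower progress of the embryos labelled MZ-KO from the early to the late stage was also examined. Across genes, which are not independent replicates, the genotype difference correlated with the WT change at a mean r of -0.34 (range -0.43 to -0.24 over 20 splits of the WT late libraries, mean Spearman's rho -0.36). No library was shared, but an offset common to all WT late embryos enters both differences with opposite sign. Such an offset alone gives a negative r, so this value cannot show slower progress. Measured against the change within embryos labelled MZ-KO, where an offset common to the late MZ-KO embryos enters with the same sign, the mean r was -0.03 (range -0.12 to 0.05). Slower progress and another effect of genotype therefore cannot be told apart. Strain, mothers and collection time stay open as untested.

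Of the genes named for the size of their rise or fall in the genotype comparisons, 47 were tested for a change of the genotype difference. Besides Trp53, 24 of these had a genotype difference that itself differed between late and early embryos, all on the log2(FPKM + 1) scale. Genes named only as list members, such as Cdkn1a and Mdm2, are not counted here. The late difference was lower for Crnkl1 (-3.12), Erich5 (-1.42), Olfr877 (-1.39), H2afx (-1.59), Calhm3 (-3.58, listed at 0 in all late embryos labelled MZ-KO, so that the value is no bound), Mir293 (-3.39), Arl4d (-2.36), Mir294 (-3.19), Defb25 (-2.70) and AA414992 (-2.15). It was higher for Ggct (0.79), Peak1os (1.23), Ralgds (1.10), Krt18 (1.58), Ier3 (4.06), Phlda2 (3.11), Nt5c (3.33), Ndufb10 (3.11), Dmac1 (2.93), Dnajb3 (2.82), Dnajc19-ps (2.85), Psmb10 (3.18), Fkbp11 (2.92) and Tex19.2 (3.02). Between early embryos and eggs, among the genes named by size in these stages and besides Trp53, the genotype difference was higher for Cnpy4 (2.92) and Crnkl1 (2.73) and lower for Ggct (-1.02).

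A library stood apart in 23 of 215 groups of libraries examined (10.7%, where chance gives about 1 in 20), measured as its gap to the nearest other library over the range of the group. WT early library 3 was highest in the mean of the p53 targets (gap 0.618 of the range), Obox4-ps33 (0.653), Obox8 (0.527), Cd63-ps (0.652), Mt1 (0.57) and Cdkn1a (0.558) and lowest in Rgs2 (0.574). In the other WT early libraries, library 7 was highest in Snora47 (0.554), library 2 highest in Olfr877 (0.551) and library 8 lowest in Alyref2 (0.623). Late MZ-KO library 5 was lowest in Nt5c (0.677) and the single library above 0 in Mir293 (1), Mir294 (1) and Mir7036b (1). Late MZ-KO library 2 was highest in Arl4d (0.677) and library 4 in Tdpoz3 (0.628). WT late library 6 was highest in Ier3 (0.766), library 4 lowest in Mdm2 (0.637), and library 4 in Dnajb3 (1) and library 2 in Iglj2 (1) were the single WT late libraries above 0. In early embryos labelled MZ-KO, library 3 in Nt5c (1), library 4 in Calhm3 (1) and library 4 in Mir294 (1) were the single libraries above 0.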

How the results depend on the processing

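The fits with voom on recovered reads, with a filter of 20 recovered reads, without the length trend and with thinned reads were chosen after seeing the data. Of the genes called in the 7 comparisons, none was called in the opposite direction under any alternative run, except 1 gene for late against early embryos with voom, where 1406 calls were shared; the late mean of the Dux-induced genes (-1.08) ran from -1.38 to -0.95 over all alternatives and left-out libraries, with an exact permutation p of at most 0.0325 before adjustment over the 6 list means, which the main value did not pass (adjusted p = 0.104). Counts moved by over 1.5 times with the filter, which changes how many genes are tested, with single libraries left out and with the other settings given here, where the cause was not tested. With no filter the counts were 6 for eggs (22), 56 for early embryos (252), 15824 for WT early to late embryo (7923) and 11 for early embryos against eggs (34). With FPKM 5 they were 14 for eggs, 1502 for late embryos (2802), 2011 for WT egg to early embryo (4423), 3554 for WT early to late embryo, 1194 for late against early embryos (2363) and 21 for early embryos against eggs. With 20 recovered reads they were 12 for eggs and 13778 for WT early to late embryo. A log2 difference of 1 or more left 58 early and 1304 late calls, the fit over all 32 libraries gave 430 early calls, voom gave 55 for early embryos against eggs, a pseudocount of 0.1 gave 8 for eggs, and leaving out KO egg library 3 for its few detected genes gave 12. The late mean of the p53 targets passed its unadjusted threshold with median-ratio scaling over all 32 libraries (-0.34 against -0.11).

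Leaving out each library gave 6 to 38 egg calls: 38, 8 and 12 without KO egg 1, 2 and 3, and 6, 7 and 7 without WT egg 1, 2 and 3. Early calls ran from 105 to 351, with 131, 136, 130 and 105 without MZ-KO early library 2, 3, 5 and 6. Late calls ran from 2407 to 2923, WT egg to early embryo from 3741 to 4501, WT early to late embryo from 7651 to 8252, and late against early embryos from 2189 to 2612. Early embryos against eggs ran from 9 to 75, with 75, 9 and 13 without KO egg 1, 2 and 3, and 13, 14 and 15 without WT egg 1, 2 and 3. The mean of the Dux-induced genes ran from 0.01 to 0.03 in eggs, -0.71 to -0.33 in early embryos, where -0.33 was without WT early library 3, and -1.27 to -0.95 in late embryos. The mean of the p53 targets ran from 0.02 to 0.08 in eggs, -0.16 to -0.06 in early embryos and -0.17 to -0.04 in late embryos. No paired analysis was possible because the deposited columns carry no replicate numbers. The alternative written for a table of counts did not apply. With 3 eggs per group, a simulated change of 1 on the log2 scale was found in 35.6% of the changed genes, all drawn from the more highly expressed ones. Smaller egg changes are therefore below what these libraries show.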

Other observations

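The gene groups in this part were chosen, and tested, after the calls in late embryos had been seen. A group of 69 tested nuclear genes held subunits of the mitochondrial respiratory chain and of ATP synthase, and complex I assembly factors such as Ndufaf1. Of these, 48 rose and 1 fell in late embryos labelled MZ-KO (median 0.80). The group's camera p of 0.0246 with an estimated correlation did not hold after adjustment over the 4 groups (adjusted p = 0.0678). Among the rises were Ndufb10 (3.14, adjusted p = 4.2e-05), Cox8c (2.69), Atp5d (2.12) and Uqcrh (2.03). The mean of the group was at least 3.08 in the 6 MZ-KO libraries and between 2.47 and 2.69 in the 6 WT libraries. Genes of the mitochondrial ribosome gave 45 rises and 0 falls among 66 (median 0.92; camera p = 0.0339 and adjusted p = 0.0678 with an estimated correlation), with Mrpl36 (2.80) and Mrps18c (2.09) as examples. Of 42 genes with proteasome symbols 21 rose and 0 fell (median 0.52), with Psmb10 (2.98) and Psma7 (1.77) among the rises. The camera p was 0.11 and the adjusted p 0.147 with an estimated correlation. These 42 are not all subunits. They include the assembly chaperone genes Psmg1 (1.18), Psmg2 (0.83) and Psmg3 (0.90, not called) and the meiotic recombination gene Psmc3ip (0.93). In the mitochondrial ribosome group and the proteasome group the mean of each of the 6 MZ-KO libraries lay above all 6 WT libraries. With median-ratio scaling the counts were 37 rises and 2 falls, 36 and 0, and 15 and 1.

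Cytosolic ribosomal protein genes went both ways, with 6 rises and 7 falls among 75 (median -0.08; 2 rises and 16 falls with median-ratio scaling), with Rpl37 (-1.12) and Rplp0 (-0.89) lower and Rpl22 (1.03) higher. The hypothesis that cytosolic ribosomal protein genes are lower as a group found no backing, with a camera p of 0.513 with an estimated correlation.

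Genes called between eggs varied between libraries of the same early group. Trav13-3 was at 22.8, 32.9, 10.6, 19.5, 21.4, 0, 0.203 and 0 FPKM in WT early libraries 1 to 8, while it was listed at 0 in all 3 WT eggs. Rnase6, on the same chromosome, was at 6, 3.98, 3.47, 4.81, 4.68, 0.083, 0.025 and 0.1 FPKM in these 8 libraries and at 0, 0.22 and 0 in the WT eggs. In early MZ-KO libraries 1 to 6, Gm47179, on chromosome 9, was at 103, 94.2, 96.2, 27.6, 26.8 and 25.1 FPKM, and Gm33962, on chromosome 6, at 5.46, 5.76, 7.1, 22.9, 20.3 and 24.4. These genes were picked after their values were seen.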
